A study of Homo sapiens with 25 samples.

How the data were processed

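Total RNA from HEK 293T cells, a human embryonic kidney line that carries the large T antigen, was measured on 25 Affymetrix HG-U133 Plus 2 arrays. Per the labels, cells were transfected against BACH1, a transcriptional repressor that binds antioxidant response elements together with small MAF proteins. The labels name 3 reagents: an esiRNA, which is an enzymatically cut pool of siRNAs against 1 transcript, and 2 single siRNAs called siRNA1 and siRNA2 here. Per the labels' protocols, a well received 200 ng of esiRNA or 300 ng of siRNA with 6 µl of the HiPerFect reagent, mock wells received the reagent without RNA, and 1 µg of total RNA was labelled. Each reagent had 3 arrays at 24 h and 3 at 72 h, and mock cells had 4 arrays at 24 h and 3 at 72 h. The series' design text lists the last 24 h mock sample (replicate 4) among the 24 h controls but under a short name that ends in 72, while its own label says 24 h, which was followed. Across genes it correlated with the other 24 h mock arrays at an r of 0.996 to 0.997 and with the 72 h mock arrays at 0.952 to 0.958. The labels call the arrays of a group biological replicates and say no more about how they were made, so p-values here measure only the spread between such samples. No transfection with a non-targeting siRNA was part of the groups.

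The deposited values are GCRMA intensity per probe set on a linear scale, per the submitters' processing notes, which give no version of that tool. GCRMA corrects for background with probe sequence, normalizes between arrays and summarizes probes. Neither the genome build nor the version of the probe annotation is given in the sources used here. The file headers of each array gave the chip lot, the fluidics station and the order of the scan days, which were used to look for batches.

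The deposited intensities were turned to log2 with no added constant. Of 54675 probe sets, 41097 carried exactly 1 gene symbol, 1801 carried several and 11777 carried none, and 62 were control probe sets. Old symbols were brought up to date through the gene identifier for 41043 probe sets, through a synonym for 43 and by the current symbol for 5, and 6 kept the array's symbol. Among probe sets with 1 symbol, the one with the highest mean over the 25 arrays stood for its gene. A gene was tested when the log2 signal of that probe set was above 4 on at least 3 arrays, which left 10672 genes. Of all probe sets but the controls, with or without a symbol, 22095 passed that filter. Some genes and positions are not analysed here.

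Differences were tested with limma 3.58.1 in R 4.3.3 on 8 group means over all 25 arrays, with 17 residual degrees of freedom and 20.03 in total after sharing the spread between genes. P-values were adjusted by the Benjamini-Hochberg method over the genes of each contrast, and a gene was called at an adjusted p below 0.05. Each reagent was compared with the mock arrays of its time, and a gene was called with all 3 siRNA types when it passed with the same sign for each of them. The mean knockdown effect was the mean of the 3 reagent groups minus mock. Its SE rests on the spread within groups, so differences between reagents are not part of it. An F-test asked whether the 3 reagent groups differed. Further contrasts compared the mean knockdown effect at 72 h with that at 24 h, and mock cells at 72 h with mock cells at 24 h. BACH1 and HMOX1 were also compared by an exact two-sided permutation test. Gene lists were tested with camera at a preset correlation of 0.01, and beside it with camera at an estimated correlation and with fry, adjusted over the lists of a contrast. Overlaps were compared with chance by Fisher's exact test across genes, which are not independent replicates.

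The groups, the tests, the lists and most alternatives were set before the data were examined. The lists held genes of heme breakdown and iron, heme synthesis, glutathione and thioredoxin (NRF2 genes), NADPH supply, CNC and small MAF factors, G1/S and replication, G2/M and mitosis, p53 targets, interferon-stimulated genes, RNA interference, the ATF4 and amino acid response, the unfolded protein response, heat shock, hypoxia and glycolysis, the respiratory chain, cholesterol synthesis, autophagy and lysosome, the proteasome, ribosomal proteins, migration, neighbours of BACH1 on its chromosome, and housekeeping genes. Markers of fibroblasts, leukocytes, endothelium and epithelium formed a separate set. Genes were named by rule. The rule took BACH1 and HMOX1, the 12 largest rises and 12 largest falls among genes called with all 3 siRNA types at a time, and up to 4 members per list and time by adjusted p. It also took the 3 largest rises and 3 largest falls called with 1 type only, the 6 largest rises and 6 largest falls of the contrasts between times, and the 5 genes with the smallest adjusted p of each F-test. The genes called at both times were named after their values were seen.

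The deposited signal was checked for sets of arrays that had been summarized apart, since GCRMA sets the level of dim probe sets from the arrays it handles together. Over the 34707 probe sets with a mean log2 signal below 4, the share that differed by more than 0.5 log2 between 2 arrays was computed for each pair. Within a set its median was 1.11%, between sets of the same time 5.29% and between times 9.69%. The 25 arrays fell into 6 such sets, which were esiRNA, siRNA1, and siRNA2 together with mock, each at 24 h and at 72 h. The sources used here do not mention these sets. A comparison of siRNA2 with mock therefore stays within a set, and every other comparison crosses sets, so that set and group cannot be told apart in it. Values for siRNA2 are given beside results for this reason.

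The file headers placed every mock array on another scan day than the knockdown arrays of its time, so that scan day and knockdown cannot be told apart. The deposited signals spanned a minimum between 1.26 and 1.75 on the arrays, and the number of arrays limits the precision of every value. The log2 signal of 3' minus 5' control probe sets, a measure of RNA integrity and labelling, was 0.14 higher in knockdown than in mock arrays at 24 h (0.74 ± 0.15, SD, n = 9, against 0.60 ± 0.07, n = 4, exact permutation p = 0.112) and 0.12 higher at 72 h (0.86 ± 0.08, n = 9, against 0.74 ± 0.03, n = 3, exact permutation p = 0.0591). Pearson's r across genes between arrays of a group lay between 0.987 and 0.999.

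The pipeline was tested on simulated data with the real group sizes and 10672 genes. Of genes shifted 1.5-fold with all 3 types, 71.6% were called at each time, of those shifted 2-fold 94% at 24 h and 89.6% at 72 h, and of those shifted 4-fold 100%, with 0 false calls. The mean knockdown effect gave 6 false calls at 24 h and 7 at 72 h. A list of 30 genes shifted by 0.2 log2 was found by camera, and 0 of 20 lists without a shift were. The simulated genes were drawn independently of each other, so this does not show how the list test behaves with correlated genes. With shuffled labels on the real arrays, 52 of 100 splits gave at least 1 list at 24 h, and 91 gave at least 3 at 72 h. Alternatives covered the filter, the choice of probe set, scaling between arrays, blocks for replicate number, fluidics station and chip lot, the 3' minus 5' measure as a covariate, other tests and thresholds, and leaving out each array or reagent. Further software was data.table (version 1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.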

Results

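The arrays gave the GCRMA signal of 10672 tested genes in HEK 293T cells at 24 h and 72 h after transfection. At each time, 3 arrays per reagent (esiRNA, siRNA1 and siRNA2, all against BACH1) stood beside mock arrays, 4 at 24 h and 3 at 72 h. The design asks which transcripts change when BACH1 is lowered, and whether reagents of different sequence against 1 transcript give the same changes.

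BACH1, the targeted repressor, was lower on each of the 18 knockdown arrays than on every mock array of its time. At 24 h the log2 signal of its brightest probe set was 6.38 ± 0.46 (SD, n = 9, from 5.62 to 6.97) after knockdown and 8.90 ± 0.06 (n = 4, from 8.83 to 8.98) in mock cells. The difference of -2.52 (SE 0.15) left 17.5% of the mock signal, with an exact two-sided permutation p of 0.0014, the smallest that 715 regroupings can give. At 72 h it was 6.44 ± 0.48 (n = 9, from 5.72 to 7.16) against 9.29 ± 0.43 (n = 3, from 8.93 to 9.76), a difference of -2.84 that left 14% of the mock signal (exact permutation p = 0.00455, the smallest that 220 regroupings can give). With esiRNA, siRNA1 and siRNA2, 18.2%, 23.5% and 12.4% of the mock signal remained at 24 h, and 15.2%, 9.6% and 18.6% at 72 h. The 2 other BACH1 probe sets sat at background in all groups, the brighter of them at group means between 2.73 and 2.99, and differed by -0.03 and -0.02 at 24 h and by 0.11 and 0.02 at 72 h.

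HMOX1, which encodes heme oxygenase 1 and is a textbook target of BACH1, was higher on every knockdown array than on every mock array of its time. Its log2 signal at 24 h was 9.19 ± 0.34 (SD, n = 9) after knockdown and 8.0 ± 0.21 (n = 4) in mock cells, a 2.27-fold rise (log2 1.18, SE 0.14, limma adjusted p = 2.76e-06). At 72 h it was 8.11 ± 0.92 (n = 9) against 5.29 ± 0.29 (n = 3), a 7.03-fold rise (log2 2.81, SE 0.16, adjusted p = 2.87e-11), while mock cells themselves lay 2.71 log2 units lower at 72 h than at 24 h (-2.71). The rise at 72 h was 12.93-fold with esiRNA, 3.19-fold with siRNA1 and 8.43-fold with siRNA2, and siRNA1 differed from esiRNA by -2.02 (adjusted p = 4.14e-08). BACH1 itself differed by -0.66 between siRNA1 and esiRNA at that time (adjusted p = 0.011), so the reagent with the least BACH1 signal at 72 h was not the one with the most HMOX1 signal. At 24 h the orders matched. HMOX1 rose 2.76-fold with siRNA2, which left the least BACH1, 2.18-fold with esiRNA and 1.94-fold with siRNA1, which left the most. The reagents lie in separately summarized sets, so set and reagent cannot be told apart here.

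**Figure D1:**
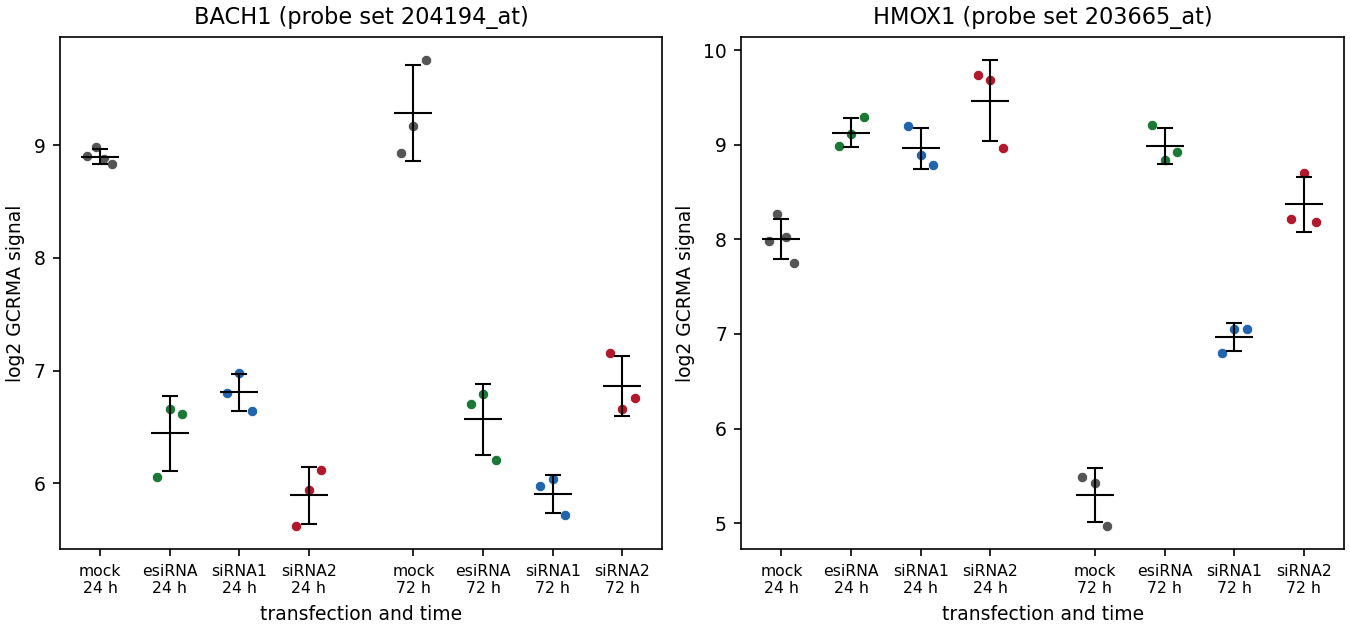
Log2 GCRMA signal of BACH1 and HMOX1 on each array in the 8 groups, with the group mean and SD as black lines. BACH1 sat between 5.62 and 7.16 on the knockdown arrays and between 8.83 and 9.76 on the mock arrays, and HMOX1 lay higher after knockdown at both times.

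A measured property of the deposited values bears on all comparisons that follow. Pairs of arrays from siRNA2 and mock differed by more than 0.5 log2 in a median of 1.06% of dim probe sets at 24 h and 1.58% at 72 h, as arrays of a group do. The median was 4.99% and 5.28% for esiRNA with mock, and 4.9% and 5.93% for siRNA1 with mock. Only siRNA2 and mock were therefore compared within a set of arrays summarized together, and for the other reagents set and group cannot be told apart.

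**Figure D2:**
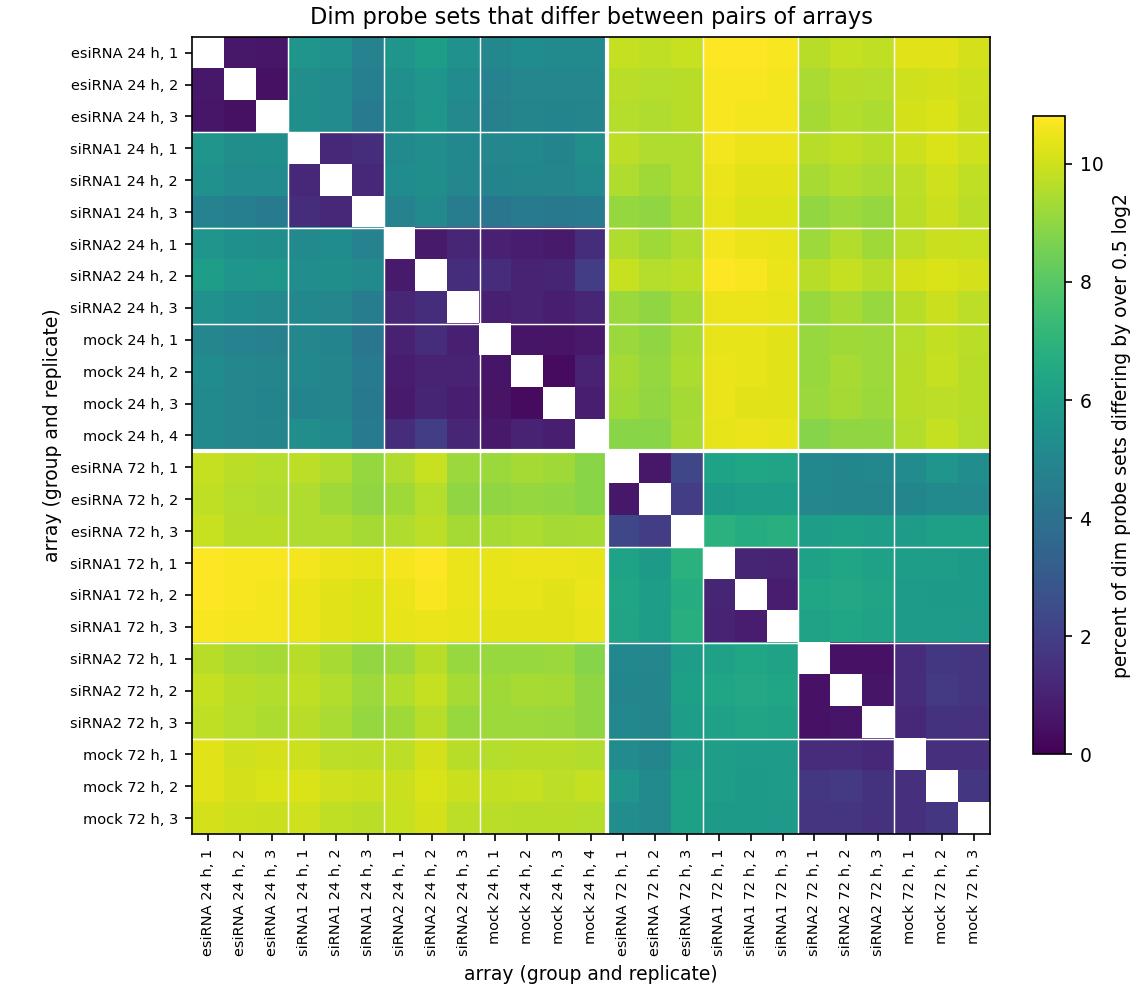
Percent of 34707 dim probe sets that differed by more than 0.5 log2 between each pair of the 25 arrays, ordered by time and group. The arrays form 6 blocks of low values, with siRNA2 and mock in a shared block at each time.

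At 24 h, ANXA3, an annexin that binds membranes in the presence of calcium, rose with all 3 siRNA types by a mean log2 of 2.11 (SE 0.16, n = 9 against 4, adjusted p = 3.95e-09), and by 2.31 with siRNA2. The histone genes H2AC6 (log2 1.90, siRNA2 3.01) and H2BC5 (1.04, siRNA2 1.78) and CCN1 (1.17, siRNA2 1.75), a secreted matrix protein that binds integrins, rose as well. Enzyme and carrier genes followed, among them GNPDA2, a glucosamine phosphate deaminase (1.07, siRNA2 1.3), MAN2C1, a cytosolic mannosidase with mock replicate 2 apart from the others (1.07, siRNA2 0.57), SLC22A23 (1.06, siRNA2 1.65) and NIPAL2 (1.04, siRNA2 0.69). After BACH1, the largest falls were those of EIF5A2, a translation factor (-1.23, SE 0.12, siRNA2 -2.37), FAR1, which makes fatty alcohols for ether lipids (-1.08, SE 0.08, siRNA2 -2.07), and RC3H2, an RNA-binding protein that promotes mRNA decay (-0.94, SE 0.07, siRNA2 -0.86). DDIT4, an inhibitor of mTOR complex 1 (-0.86, siRNA2 -1.0), INSIG1, which retains sterol regulators in the endoplasmic reticulum (-0.78, siRNA2 -0.76), KLHL5 (-0.78, siRNA2 -0.94), MTR, the methionine synthase (-0.70, siRNA2 -0.39), and IDI1 of isoprenoid synthesis (-0.58, siRNA2 -0.73) fell too.

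In all, 309 genes were called with all 3 siRNA types at 24 h, 278 higher and 31 lower, of which 31 changed at least 1.5-fold with each type and 2 at least 2-fold with each. The median absolute log2 change of their mean over types was 0.45. Independent calls with the counts of each type would share 46.8 higher and 9.54 lower genes. Simulated data without any effect but with the shared mock arrays gave 0. Those data held only the spread within groups, and at most 1 gene was shared by a pair of types. They do not show how shared mock arrays or an offset between sets act on these calls. Given the genes shared by esiRNA and siRNA1, siRNA2 would share 123 higher ones by chance (Fisher's exact one-sided p = 2.51e-45) and 33.3 lower ones, so that the 31 lower genes were no excess (p = 0.693). These p-values take the calls as independent, while all types share their mock arrays. The mean knockdown effect called 3089 genes, 1970 higher and 1119 lower, by the spread within groups. With differences between reagents put into the spread, it called 292. The count of 309 was 205 without esiRNA 24 h replicate 3, 206 without mock 24 h replicate 4 and 192 with the 3' minus 5' measure as a covariate, a measure that was 0.14 higher in the knockdown arrays. All mock arrays of that time were scanned on a day of their own, so scan day and knockdown cannot be told apart.

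Genes of cholesterol synthesis fell at 24 h. Of 19 tested members, 0 were higher and 8 lower over all genes tested (1 higher and 8 lower adjusted over the list alone), the median log2 change was -0.19 and camera gave an adjusted p of 4.13e-05. The adjusted p = 0.43 with an estimated correlation, and the list passed with each siRNA type at the set correlation only. The adjusted p was 0.0264 with esiRNA (0.87 with an estimated correlation), 0.00561 with siRNA1 (0.48) and 3.71e-05 with siRNA2 (0.21, 0 higher and 6 lower). INSIG1, IDI1 and HMGCS1 (-0.58, SE 0.06), the synthase that starts the pathway, fell with all 3 types. MSMO1 (-0.39, but 0.04 without siRNA2) and SQLE (-0.36), enzymes of later steps, were lower in the mean. It was the only list of 22 that passed for the mean knockdown effect at 24 h. Fry, which asks whether a list's genes move one way on balance, passed 4 lists, cholesterol synthesis (adjusted p = 7.95e-05), heme breakdown and iron (0.000729), RNA interference (0.00308) and p53 targets (0.006).

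Among the lists closest to BACH1, heme breakdown and iron had 8 of 16 members higher and 2 lower at 24 h (median 0.15, adjusted p = 0.148). The transferrin receptor TFRC (0.47, SE 0.07) rose with all 3 types, as HMOX1 did. In the mean effect the ferritin light chain FTL rose by 0.17 (SE 0.04) and the heme carrier SLC48A1 by 0.63 (SE 0.15), the latter called with esiRNA (1.47) but not with siRNA1 or siRNA2 (0.21 each). The glutathione and thioredoxin list had 3 of 33 members higher and 9 lower (median -0.02, adjusted p = 0.139, and lower at 0.0365 after quantile normalization). In it, GCLM, the modifier subunit of the enzyme that starts glutathione synthesis, rose by 0.75 and SQSTM1, a receptor of selective autophagy, by 0.60, while the thioredoxin reductase TXNRD1 (-0.64) and the cystine carrier SLC7A11 (-0.55) fell in the mean effect, called with siRNA1 and siRNA2. Thioredoxin itself, TXN, was lower with siRNA2 (-1.42) and was not called with esiRNA (-0.08) or siRNA1 (-0.05). CNC and small MAF factors had 2 higher and 2 lower of 9 (median -0.03, adjusted p = 0.326), heme synthesis 2 and 0 of 12 (0.01, adjusted p = 0.921; ALAS1, its first enzyme, 0.31) and NADPH supply 0 and 1 of 12 (0.02, adjusted p = 0.371).

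No further list passed camera at 24 h for the mean knockdown effect. The RNA interference list had 6 of 14 members higher and 1 lower (median 0.22, adjusted p = 0.275), with AGO1 at 0.69 and TNRC6A at 0.58, and the p53 list 9 and 2 of 25 (0.11, adjusted p = 0.275), with the nuclease AEN at 0.59. The interferon list, which double-stranded RNA can raise, had 9 of 40 members above the filter, 1 higher and 3 lower (-0.11, adjusted p = 0.249). The ATF4 list had 1 higher and 8 lower of 35 (-0.02, adjusted p = 0.139), G1/S 1 and 4 of 42 (0.02, 0.326), G2/M 12 and 1 of 45 (0.09, 0.249), heat shock 4 and 1 of 18 (0.09, 0.425), and hypoxia 4 and 4 of 32 (-0.04, 0.368). Autophagy had 5 and 2 of 34 (0.02, adjusted p = 0.921), migration 1 and 1 of 12 (0.13, 0.921), the chromosome neighbours 1 and 3 of 13 (-0.09, 0.275), and the respiratory chain 2 and 3 of 47 (-0.01, 0.43). The proteasome (2 and 1 of 27), ribosomal proteins (3 and 2 of 37), housekeeping genes (3 and 0 of 14) and the unfolded protein response (1 and 1 of 28) each had an adjusted p of 0.921.

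At 72 h, HMOX1 showed the largest rise among genes called with all 3 siRNA types, and SAMD4B, an RNA-binding protein, followed with a mean log2 of 1.95 (SE 0.24, n = 9 against 3, adjusted p = 3.22e-06, siRNA2 2.09). SLC35G1 (1.55, siRNA2 0.97), SLC68A1 (1.5, siRNA2 1.59), the nucleosome assembly gene NAP1L2 (1.49, SE 0.11, siRNA2 1.65), the transcription factor ATF7 (1.20, siRNA2 1.39) and DPF3, a subunit of a chromatin remodelling complex (1.18, siRNA2 1.38), rose as well. After BACH1, the largest fall was that of XK, a membrane protein of red cells and muscle (-2.01, SE 0.08, adjusted p = 1.72e-13, siRNA2 -1.38). SLC1A4, a carrier of neutral amino acids (-1.72, SE 0.22, siRNA2 -3.03), PDIA4, a protein folding enzyme of the endoplasmic reticulum (-1.24, SE 0.30, siRNA2 -1.27), PCK2, the mitochondrial phosphoenolpyruvate carboxykinase (-1.16, SE 0.13, siRNA2 -1.82), and the transcriptional coactivator CITED1 (-1.32, siRNA2 -1.5) fell with it. RPL22L1, a paralog of a ribosomal protein (-1.03, siRNA2 -1.73), and WIPI1 of autophagosome formation (-1.06, siRNA2 -1.03) were also lower with each type.

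At that time 304 genes were called with all 3 siRNA types, 96 higher and 208 lower, of which 46 changed at least 1.5-fold with each type and 10 at least 2-fold with each. Their mean over types had a median absolute log2 change of 0.53. Independent calls would share 37.1 higher and 82.3 lower genes. Simulated data without an effect gave 0, but held only the spread within groups. They do not show how shared mock arrays or an offset between sets act on these calls. Given the genes shared by esiRNA and siRNA1, siRNA2 would share 91.7 higher ones by chance, so that the 96 higher genes were no clear excess (Fisher's exact one-sided p = 0.327), and 143 lower ones (p = 1.34e-09). Both p-values take the calls as independent, while all types share their mock arrays. The mean knockdown effect called 3578 genes, 1417 higher and 2161 lower, by the spread within groups. With differences between reagents put into the spread, it called 266. The split by direction depended on the scaling, with 41 higher and 344 lower shared genes after centring each array on its median, which moved the median change of all genes to -0.11. After quantile normalization it was 269 and 110, and of the mean calls 39.6% were higher against 23.4% and 57%. Scan day and knockdown cannot be told apart, and a fit with chip lot as a block called 1136 shared genes, 765 higher and 371 lower.

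Genes of the ATF4 and amino acid response were lower at 72 h in the mean knockdown effect. With shuffled labels, 9 of 100 splits gave a camera p as small for this list, so chance cannot be excluded. Of 35 tested members, 1 was higher and 28 lower, over all genes and adjusted over the list alone, with a median log2 change of -0.41 and a camera adjusted p of 8.42e-09 (adjusted p = 0.48 with an estimated correlation). SLC1A4 and SHMT2, the mitochondrial serine hydroxymethyltransferase (-0.75, SE 0.09), fell with all 3 types, and the asparagine synthetase ASNS (-0.71, SE 0.07) and PSAT1 of serine synthesis (-0.54, SE 0.06) fell in the mean. With siRNA2 alone 1 member was higher and 31 lower (median -0.79, adjusted p = 1.49e-17, and 0.051 with an estimated correlation), and with siRNA1 4 and 22 (-0.38, adjusted p = 0.016, and 0.95 with an estimated correlation). With esiRNA 4 members were lower and 1 higher (median -0.10), and the list did not pass, though the difference between reagents was not tested for the list.

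The unfolded protein response list had 0 of 28 members higher and 13 lower at 72 h (1 and 17 adjusted over the list alone, median -0.49, camera adjusted p = 0.00759), with an adjusted p = 0.96 with an estimated correlation. PDIA4 and SEL1L (-0.80, SE 0.17), a part of the degradation machinery of the endoplasmic reticulum, fell with all 3 types, and the chaperones DNAJB11 (-0.73, SE 0.17) and CANX (-0.38, SE 0.09) fell in the mean. The call ended without mock 72 h replicate 3 (adjusted p = 0.873) and without siRNA2 (0.0721). Cholesterol synthesis had 1 of 19 members higher and 9 lower (median -0.24, camera adjusted p = 0.0213, and adjusted p = 0.96 with an estimated correlation), and its call ended without siRNA1 (0.493), with siRNA2 alone (0.14) and with the 3' minus 5' covariate (0.0672). With shuffled labels, 44 of 100 splits gave a camera p as small for the unfolded protein response and 20 for cholesterol synthesis. Fry passed 10 lists at 72 h, among them ATF4, the unfolded protein response and cholesterol synthesis. The others were heme breakdown and iron, heme synthesis, NADPH supply, CNC and small MAF factors, G1/S, autophagy and migration.

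**Figure D3:**
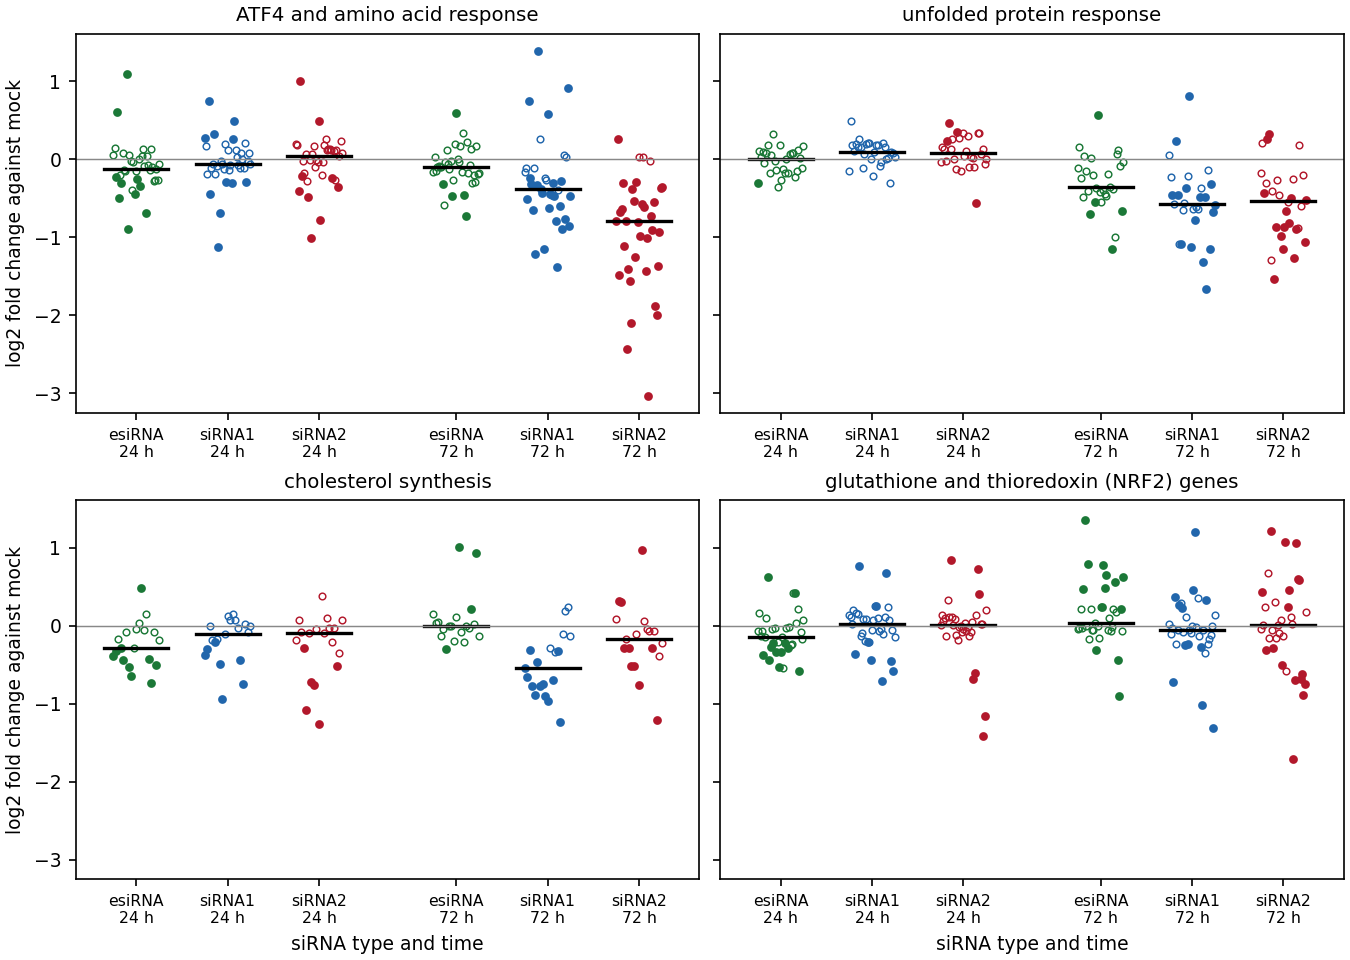
Log2 change against mock of each member of 4 lists by siRNA type and time, filled where the adjusted p was below 0.05 and open elsewhere, with the median as a black line. The ATF4 members lay at a median of -0.79 with siRNA2 at 72 h and at -0.10 with esiRNA.

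Lists closest to BACH1 went both ways at 72 h. None of them passed camera, while fry passed all of them but glutathione and thioredoxin. The adjusted p-values that follow are those of camera. Heme breakdown and iron had 4 of 16 members higher and 2 lower (median 0.11, adjusted p = 0.378). The glutathione and thioredoxin list had 7 of 33 higher and 7 lower (8 and 7 adjusted over the list alone, median 0.04, adjusted p = 0.619), with GCLM at 0.76 and MGST1, a microsomal glutathione transferase, at 0.59, against SLC7A11 at -0.93 and TXNRD1 at -0.71. Heme synthesis had 1 and 5 of 12 (-0.19, adjusted p = 0.504; ALAS1 0.31), CNC and small MAF factors 2 and 1 of 9 (0.01, 0.436), and NADPH supply 0 and 4 of 12 (-0.21, 0.436). In the G1/S list 1 member was higher and 12 of 42 lower (-0.04, adjusted p = 0.504), among them the replication licensing factors CDC6 (-0.83) and ORC1 (-0.56), and in the G2/M list 6 and 5 of 45 (0.02, 0.504). Migration had 1 and 5 of 12 (-0.10, adjusted p = 0.484), with the chemokine receptor CXCR4 at -0.83, and the respiratory chain 4 and 11 of 47 (-0.06, 0.619).

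The remaining lists at 72 h did not pass camera for the mean knockdown effect, though autophagy passed fry. Autophagy had 5 members higher and 12 lower of 34 (median -0.15, adjusted p = 0.411), hypoxia 4 and 9 of 32 (-0.08, 0.68), p53 6 and 2 of 25 (0.02, 0.504), heat shock 3 and 3 of 18 (0.06, 0.436), and the interferon list 2 and 0 of 9 (0.06, 0.504). Ribosomal proteins had 1 and 6 of 37 (-0.01, adjusted p = 0.837), RNA interference 2 and 3 of 14 (-0.02, 0.837), the chromosome neighbours 2 and 3 of 13 (-0.05, 0.965), and housekeeping genes 2 and 1 of 14 (0.01, 0.619). The proteasome had 0 and 1 of 27 (-0.04, adjusted p = 0.715), the member being PSMB5 at -0.74.

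HMOX1, GCLM, SQSTM1, NAP1L2, SEMA3C, BCAT2 and CEP15 were called higher with all 3 siRNA types at both times. HMOX1, GCLM and SQSTM1 are textbook genes with antioxidant response elements. GCLM rose by 0.75 (SE 0.07) at 24 h and 0.76 (SE 0.08) at 72 h (siRNA2 0.85 and 1.22), SQSTM1 by 0.60 and 0.50 (though the mean of its probe sets gave -0.01 at 24 h), NAP1L2 by 0.59 and 1.49, the secreted guidance protein SEMA3C by 0.65 and 0.69, and BCAT2, a mitochondrial aminotransferase of branched-chain amino acids, by 0.44 and 0.56. BACH1, EIF5A2, KLHL5, FAM8A1, DPY19L1, MTR, FAR1, RAB11FIP2 and SLC38A2 were lower with all 3 types at both times, EIF5A2 by a log2 change of -1.23 and -1.20 and the amino acid carrier SLC38A2 by -0.28 and -0.55. The 7 higher genes stood against 2.5 expected from the counts at each time (Fisher's exact one-sided p = 0.0125) and the 9 lower against 0.6 (p = 4.75e-09), and 2 genes went opposite ways against 5.42 expected. Given the genes shared by esiRNA and siRNA1 at both times, 3.89 higher and 4.28 lower ones would be shared with siRNA2 by chance (Fisher's exact one-sided p = 0.0936 and 0.0268). For all 16 together p was 0.00791, and 0.0162 without BACH1. The p-values for the overlap with siRNA2 take the calls as independent, while all types share their mock arrays. The count was 10 after median centring (2 higher, HMOX1 and BCAT2, without GCLM and SQSTM1), 38 after quantile normalization (26 higher) and 66 with chip lot as a block, which rests on esiRNA 72 h replicate 3 alone. GCLM left the count without siRNA1 72 h replicate 1, 2 or 3 and without mock 72 h replicate 3, while HMOX1 and SQSTM1 stayed with any 1 array left out.

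**Figure D4:**
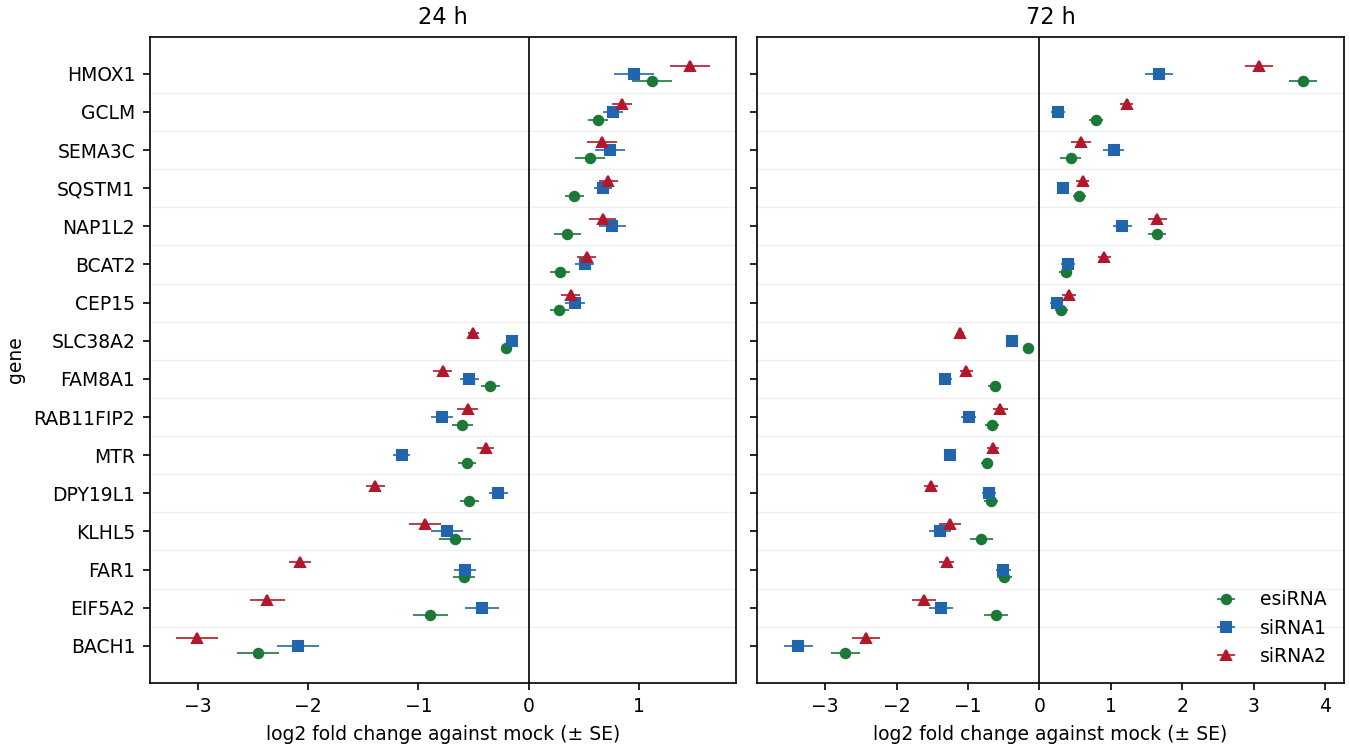
Log2 change against mock by siRNA type at 24 h and 72 h for the 16 genes called with all 3 types at both times, with the SE as bars. HMOX1 has the largest rises and BACH1 the largest falls in the mean.

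Many genes were called with a single reagent at 24 h. Genes called with 1 type only included TMEM255A (-3.54, SE 0.23), TMA16 (-2.69, SE 0.10) and PAQR3 (-2.15, SE 0.08) with siRNA2. With siRNA1 they included STS, the steroid sulfatase (-2.44, SE 0.21), and PPIF, the mitochondrial cyclophilin (-1.87, SE 0.08), and with esiRNA PITX1 (-2.28, SE 0.26) and HOXD4 (-2.26, SE 0.07), homeobox genes. In total 2869 genes were called with esiRNA (1434 higher, 1435 lower), 3444 with siRNA1 (2335 and 1109) and 2274 with siRNA2 (1591 and 683), of which 1113, 1326 and 1052 were called with no other type. After quantile normalization, 1205 of the siRNA2 calls were higher and 866 lower. Without siRNA2 24 h replicate 2 the siRNA2 count was 1478, and the esiRNA count was 1432 with the 3' minus 5' measure as a covariate (0.87 in esiRNA against 0.60 in mock arrays). It was 1738 with fluidics station as a block, all esiRNA arrays of that time having been run on station 2 and all mock arrays on station 1.

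At 72 h, SLC7A3, a carrier of cationic amino acids (-2.34, SE 0.38), DDIT4 (-2.09, SE 0.12) and the sulfatase SULF1 (-1.99, SE 0.26) were called lower with siRNA2 only. INSM1 (-2.33, SE 0.18) and ENDOD1 (-2.32, SE 0.21) were called lower with siRNA1 only, and ZNF37BP (-1.62, SE 0.21) with esiRNA only. In total 3374 genes were called with esiRNA (1796 higher, 1578 lower), 4554 with siRNA1 (1588 and 2966) and 3483 with siRNA2 (1481 and 2002), of which 945, 1804 and 1402 were called with no other type. After quantile normalization the splits were 2251 and 1453, 2171 and 2319, and 2483 and 1605. After median centring they were 1217 and 2032 for esiRNA and 931 and 2335 for siRNA2.

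HMOX1, ANXA3 and FAR1 were among the genes shared by all pairs of reagents at 24 h. The pairs shared more calls than independent calls would, apart from the lower genes of esiRNA and siRNA2. esiRNA and siRNA1 shared 827 higher and 521 lower genes (314 and 149 expected), esiRNA and siRNA2 376 and 80 (214 and 91.8), and siRNA1 and siRNA2 700 and 90 (348 and 71). Pearson's r across genes, which are not independent replicates, was 0.497, 0.0997 and 0.19 for these pairs, against means of 0.449, 0.447 and 0.433 in simulated data without an effect, where the shared mock arrays alone give a correlation. Those data held only the spread within groups, so a lower r in the real data does not show less agreement than noise gives. The covariance across genes was 0.0672, 0.0116 and 0.0229, against simulated means of 0.00769, 0.00804 and 0.00784. With separate mock arrays for each reagent, r ranged over 6 splits from 0.384 to 0.466 for esiRNA and siRNA1, from -0.0643 to 0.126 for esiRNA and siRNA2, and from 0.0324 to 0.197 for siRNA1 and siRNA2.

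At 72 h, PCK2, XK and HMOX1 were among the genes shared by all pairs. esiRNA and siRNA1 shared 661 higher and 762 lower genes (267 and 439 expected), esiRNA and siRNA2 432 and 470 (249 and 296), and siRNA1 and siRNA2 204 and 620 (220 and 556). The correlations across genes were 0.39, 0.22 and 0.0365, against 0.487, 0.505 and 0.464 in the simulations, which held only the spread within groups. The covariances were 0.0793, 0.0382 and 0.00735, against simulated means of 0.0101, 0.0105 and 0.00976. For siRNA1 and siRNA2 the higher genes were no excess, and the covariance lay below the simulated mean. The 3 mock arrays of that time were not split, so part of any excess may come from the shared controls.

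The 3 reagents differed from each other in 5080 genes at 24 h and 7560 at 72 h by the F-test. Genes with the smallest adjusted p were TGM5, CLPS, ZHX3, LAT and MYO7B at 24 h and CRMP1, GPRC5C, LOC100505918, TCEANC and SMIM29 at 72 h. These lay at mock level with siRNA2, between -0.02 and 0.00 at 24 h and between 0.02 and 0.13 at 72 h, while the largest change with another reagent was 1.11 to 1.96 and 1.88 to 2.81. Their mean log2 signal in mock cells was 4.14 to 5.2 at 24 h and 2.7 to 6.64 at 72 h, so some sat near background. Among all genes of the F-test, 69% at 24 h and 60.2% at 72 h were not called for siRNA2 against mock. Of all tested genes, siRNA2 called 21.3% at 24 h and 32.6% at 72 h, smaller shares than among the genes of the F-test. The level of the named genes with siRNA2 is thus not that of the F-test genes at large. The 3 reagents stood in 3 separately summarized sets, so set and reagent cannot be told apart here.

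The knockdown effect differed between 72 h and 24 h for HMOX1, whose rise was larger at 72 h by 1.63 (adjusted p = 8.85e-06). It also differed for PCK2 (-1.24) and RPL22L1 (-1.12), which fell with all 3 types at 72 h and lay at -0.15 and -0.06 with siRNA2 at 24 h, where RPL22L1 rose with esiRNA (0.26). For SLC1A4 (-1.54, SE 0.29) siRNA2 gave 0.14 at 24 h and -3.03 at 72 h, while esiRNA gave a fall at both times (-0.68 and -0.73). The largest differences were those of AP3B2 (2.21, SE 0.27), DOK1 (1.90, SE 0.08) and NBL1 (1.88, SE 0.05) upward and XK (-2.01, SE 0.11) and PLPP5 (-1.89, SE 0.61) downward. With siRNA2 DOK1 was at -0.10 and 0.01 and NBL1 at -0.03 and 0.01. Mock 24 h replicate 4 lay apart from the others for AP3B2 (5.53 against 5.5) and DOK1 (7.02 against 6.81 to 6.82), by far less than the differences between times. In total 3055 genes differed, 1004 upward and 2051 downward, and 1671 with siRNA2 alone, 377 and 1294. The splits were 671 and 3155 after median centring and 1349 and 1266 after quantile normalization. Of the lists, ATF4 passed downward (0 up and 23 down of 35, median -0.35, camera adjusted p = 0.0018, and adjusted p = 0.96 with an estimated correlation). With siRNA2 alone 0 of its members differed upward and 27 downward (median -0.84, adjusted p = 5.32e-18, and 0.0459 with an estimated correlation). For the mean effect, 27 of 100 splits with shuffled labels gave a camera p as small for this list.

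Mock cells at 72 h had lower levels of CLU, a secreted chaperone (-4.67, SE 0.07, n = 3 against 4), and ANXA1, an annexin (-3.85, SE 0.21), than at 24 h. They had higher levels of RARB and CYP26A1, genes of retinoid response and breakdown (4.12, SE 0.07, and 3.66, SE 0.08), and of BHLHE40 (3.45, SE 0.20). Genes of the ATF4 response were higher, 33 of 35 up and 1 down (median 0.83, adjusted p = 1.11e-13, and adjusted p = 0.13 with an estimated correlation), with ASNS at 1.70 and CHAC1, which breaks down glutathione, at 2.86. Hypoxia genes were higher (17 up and 7 down of 32, median 0.54, adjusted p = 0.00108), among them BNIP3 at 1.54 and PDK1 at 2.12, as were those of the unfolded protein response (10 up and 2 down of 28, 0.20, adjusted p = 0.0102), and heat shock genes were lower (0 up and 18 down of 18, -0.66, adjusted p = 0.00108). Each of these 3 lists had an adjusted p = 0.99 with an estimated correlation. In total 7203 genes differed, 2396 up and 4807 down, with 3334 and 3497 after median centring and 3448 and 3708 after quantile normalization. The mock arrays of the 2 times were scanned on different days and summarized apart, so time cannot be told apart from day or set.

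Few markers of other cell types passed the filter. Of leukocyte markers 0 of 8 passed the filter, of endothelial markers 1 of 6 (PECAM1, mean log2 4.39), of fibroblast markers 2 of 8 (COL1A1, 7.39) and of epithelial markers 3 of 9, among them SFN at 8.79 and CD24 at 5.89. At 24 h 1 endothelial marker was called higher in the mean knockdown effect, and at 72 h 2 epithelial markers were called higher and 1 fibroblast marker lower.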

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

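The tests of run order, of a response to any siRNA, of the 3' minus 5' measure, of separately summarized sets for the share of rises and for the ATF4 list, and of chip lot and scan day for siRNA2 were chosen after the results were seen.

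HMOX1 was among 16 genes that were called in 1 direction with all 3 siRNA types at both times. An effect of the order in which mock arrays were run is argued against, since mock arrays were scanned before the knockdown arrays at 72 h and after them at 24 h, and 2 genes went opposite ways against 16 that did not. Sets summarized apart predicted no more genes shared with siRNA2, which lies in the set of mock, than the 8.17 expected of independent calls, and the 16 exceeded this (Fisher's exact one-sided p = 0.00791, and 0.0162 without BACH1, whose fall is the knockdown itself), with p = 0.0936 for the higher and 0.0268 for the lower genes (0.0598 without BACH1). The bound of 0.05 set in advance applied to each direction. It was met by the lower genes with BACH1 but not by the higher ones, so this test does not decide. The test also took the calls as independent, while all types share their mock arrays. In simulated data with only the spread within groups, that sharing gave a mean r of 0.447 and 0.433 between siRNA2 and the other types at 24 h, but at most 0 genes called at both times. Those data held no offset between sets, so they do not show how shared mock arrays act on genes that an offset moves, and these sets remain open. A response to transfected siRNA of any sequence remains open too, since no non-targeting siRNA was used and an adjusted p of 0.249 for the interferon list at 24 h covers 9 of its 40 members only, and so does lower BACH1, which no test here separates from the others.

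Of the genes called with all 3 siRNA types at 24 h, ANXA3 and HMOX1 among them, 90% were higher. With the 3' minus 5' measure as a covariate 90.1% were higher, though the count itself was 192. With it siRNA1 still called 2046 genes higher and 902 lower, siRNA2 1723 and 714, and esiRNA 738 and 694. This argues against that measure as the whole cause of the rises with siRNA1 and siRNA2. Over 6 pairs of mock arrays the lowest share was 82.2%, so most were higher whichever pair was used. The bound for both shares was 60%, which was loose. Independent calls with the counts of each type would already give 46.8 higher and 9.54 lower genes, so these shares alone decide little, also for single mock arrays. Sets summarized apart remain open for the direction, since 70% of the siRNA2 calls, made within a set, were higher in the deposited scaling but 58.2% after quantile normalization. Scan day cannot be told apart from knockdown and stays open, as do a response to any siRNA and an effect of lower BACH1, which no array of these groups tells apart.

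SLC1A4, ASNS and other members of the ATF4 list were lower at 72 h. Scaling is argued against, since the highest camera adjusted p over median centring and quantile normalization was 1.29e-07 at the preset correlation. Sets summarized apart are argued against for siRNA2 only, since camera gave an adjusted p of 1.49e-17 for it within its set (0.051 with an estimated correlation). They remain open for esiRNA and siRNA1, whose comparisons with mock cross sets. An offset of chip lot or scan day as the whole cause of the fall with siRNA2 is argued against, since its arrays lay at -0.92, -0.81 and -0.74 and the 2 esiRNA arrays of the same lot and day at -0.13 and -0.14, with a smallest difference of -0.40 over 3 scalings against 0.26 at most within a group, though these arrays come from different sets. Lot and scan day remain open for esiRNA and siRNA1 and for a part of the fall with siRNA2, since only esiRNA replicate 3 (0.06 above mock) shared the lot of the mock arrays and none shared their day, and 9 of 100 regroupings gave a list p as small, so chance cannot be excluded for this list. From 24 h to 72 h the list's median moved by 0.83 in mock cells, 0.84 with esiRNA, 0.47 with siRNA1 and 0.07 with siRNA2, which is consistent with a smaller rise in culture with the single siRNAs, and a biological cause of that was not tested.

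In the 4 mock arrays at 24 h, the array farthest from the others stood apart by Dixon's ratio for 12 of the 56 genes looked at, and chance picks about 1 in 20 groups. Replicate 4, which the series' design text names with a 72 and its label with 24 h, gave 7 of the 12, and it correlated at 0.996 to 0.997 with the other 24 h mock arrays and at 0.952 to 0.958 with those of 72 h. The log2 values of these arrays, with those of the other mock arrays in brackets, were 5.07 (4.74) for STX17-DT, 5.71 (5.05) for DPF3, 5.53 (5.5) for AP3B2, 7.02 (6.81 to 6.82) for DOK1, 6.88 (6.79) for TSPAN9, 4.91 (4.82 to 4.83) for CFAP70 and 3.49 (3.41) for TMEM175 in replicate 4. They were 3.71 (4.03 to 4.06) for MAN2C1, 3.91 (4.18 to 4.22) for ZNF211 and 5.93 (6.02) for BICD1 in replicate 2, 4.24 (3.6 to 3.7) for SH2D3A in replicate 1 and 3.01 (2.84 to 2.86) for HTRA1 in replicate 3. Several of these offsets were small and stood apart because the other values nearly coincided.

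The knockdown effect differed between the times, by the test of the difference itself, for 40 of these 56 genes and for a list. Many of the 56 were named for a large change at 1 time or for this difference, so 40 of 56 is no share of genes at large, and over all genes 3055 of 10672 differed. Among genes with a higher effect at 72 h, the difference was 1.63 for HMOX1, 1.78 for SAMD4B, 1.11 for SLC35G1, 1.33 for SLC68A1, 0.89 for NAP1L2, 1.64 for STX17-DT, 1.35 for DPF3, 1.59 for SMIM29, 0.99 for BICD1 and 1.02 for EMP3. For genes that fell at 24 h it was 0.43 for RC3H2, 0.36 for INSIG1, 0.5 for CAMK4 and 0.33 for KCTD12. It was 2.21 for AP3B2, 1.9 for DOK1, 1.88 for NBL1, 1.85 for SLC13A4, 1.83 for TSPAN9 and 1.8 for CFAP70, of which siRNA2 showed a change at 72 h for AP3B2 (1.28) and CFAP70 (0.23) only. Among genes with a lower effect at 72 h, it was -1.13 for ANXA3, -1.19 for H2AC6, -0.6 for CCN1, -0.67 for MAN2C1, -0.72 for GNPDA2, -1.44 for SLC22A23, -1.25 for NIPAL2 and -1.14 for TCHP. It was -2.01 for XK, -1.54 for SLC1A4, -1.16 for CITED1, -1.31 for PDIA4, -1.24 for PCK2, -1.09 for PLEKHG4, -1.12 for RPL22L1 and -0.44 for FAM8A1. The last of these were -1.89 for PLPP5, -1.68 for SH2D3A, -1.58 for HTRA1 and -1.53 for TMEM175. With siRNA2 alone the direction was the other one for SH2D3A (0.075) and TMEM175 (0.081). The ATF4 list had a median difference of -0.35, for which 27 of 100 regroupings gave a camera p as small.

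Regrouping the arrays within each time tested whether chance could give the counts, and 1 split of each family, the real one, gave a count as large as the real count for all gene counts. Over 100 splits chance can be excluded for genes called with all 3 siRNA types at 24 h (309, highest other 71), at 72 h (304, highest other 10) and at both times (16, highest other 0), for the mean knockdown effect at 24 h (3089, highest other 505) and 72 h (3578, highest other 763), for the difference between times (3055, highest other 167) and for genes that differed among siRNA types (5080, highest other 2951, and 7560, highest other 4738). Over 35 splits it can be excluded for esiRNA at 24 h (2869, highest other 1380), siRNA1 (3444, highest other 1755), siRNA2 (2274, highest other 739) and the mock times (7203, highest other 5491). Regrouping puts any difference between groups into the spread, which lowers the other counts. A difference between sets summarized apart or between scan days could pass in the same way. What is excluded is thus a chance choice of labels, and these splits do not separate knockdown from set or day. At 72 h 10 splits are too few for a share under 0.05, with 3374 genes for esiRNA (highest other 178), 4554 for siRNA1 (highest other 4) and 3483 for siRNA2 (highest other 13). For the number of lists that passed, chance cannot be excluded, since 52 of 100 splits gave at least 1 list at 24 h (highest other 6) and 91 gave at least 3 at 72 h (highest other 7). For single lists, 3 of 100 splits gave a p as small for cholesterol synthesis at 24 h, 20 at 72 h, and 44 for the unfolded protein response.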

How the results depend on the processing

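Chip lot as a block, the count of genes called at both times, the lists with the 3' minus 5' covariate and siRNA2 alone for the difference between times were chosen after seeing the data. Of the 285 results for single genes, 4477 values under other settings held 3851 with the same direction and side of the threshold, 547 in the same direction but no longer past it, 57 newly past it and 22 reversed. With each array left out, 3704 of 3862 were the same, 142 were no longer past the threshold, 16 were newly past it and 0 reversed. The lists of cholesterol synthesis at 24 h and ATF4 at 72 h lost their call with an estimated correlation and under no other setting run for the mean effect, though the ATF4 list did not pass with esiRNA taken alone. GCRMA signal near background limits the smallest changes that could be seen, and 13 of the 309 genes shared at 24 h and 38 of the 304 at 72 h had a mean log2 signal under 6.

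Some settings change counts by their construction. Without the filter on dim probe sets, more genes were tested, and the mean knockdown effect called 4728 at 24 h and 7364 at 72 h, esiRNA 4894 and 6274, siRNA1 at 24 h 5312, the F-test at 24 h 8063, the difference between times 6994 and the mock times 13987, with 4 lists at 24 h and 11 at 72 h. The stricter filter gave 1876 for esiRNA at 24 h. With all probe sets as features, the shared calls were 474 at 24 h, 696 at 72 h and 30 at both times, the mean effect 6309 and 7603, esiRNA 6867 and 7666, siRNA1 7346 and 9439, siRNA2 3639 and 6504, the F-test 11449 and 15214, the difference between times 6266 and the mock times 14901. With a minimum fold of 1.5, fewer calls qualify, and the shared calls were 31 at 24 h, 46 at 72 h and 3 at both times, the mean effect 374 and 637, esiRNA 868 and 1260, siRNA1 1034 and 1733, siRNA2 648 and 1293, the F-test 2276 and 4015, the difference between times 962 and the mock times 3761. With at least 2 of the 3 siRNA types, 1976 genes were called at 24 h, 2541 at 72 h and 360 at both times.

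For the counts in this paragraph the cause was not tested. The genes at both times numbered 10 after median centring, 38 after quantile normalization, 9 with fluidics station as a block, 66 with chip lot as a block and 0 with a Welch test per gene, and of the 16 genes 8, 16, 8 and 12 remained in the first 4. With the arrays of each time alone, the shared calls were 490 at 24 h and 135 at 72 h. Chip lot as a block gave 1136 shared calls at 72 h, and fluidics station as a block 1738 esiRNA calls at 24 h. The chip lot block rests on esiRNA 72 h replicate 3 alone, the only array that differed in lot from others of its group. The 3' minus 5' covariate gave 192 shared and 1432 esiRNA calls at 24 h. With 2 groups per time, which puts differences between reagents into the spread, the mean effect called 292 at 24 h and 266 at 72 h. A Welch test per gene gave 69 and 2 shared calls, 1478 and 205 for the mean effect, 1357 and 1417 for siRNA1, 1037 and 101 for siRNA2, and 478 for esiRNA at 72 h. Of the lists, 0 passed at either time with an estimated correlation, and fry passed 4 and 10. With siRNA2 alone, 1671 genes differed between times. The replicate block gave 179 shared calls at 24 h, and the arrays share only a number, since same-numbered arrays correlated at -0.452 to 0.367 at 24 h, with 2 of 18 pairs above 0.1, and at -0.126 to 0.09 at 72 h, with 0 of 18. That block moved no other total by more than 1.5 times, but by direction the higher genes went from 1591 to 961 with siRNA2 at 24 h, from 1970 to 1253 in the mean effect at 24 h and from 7 to 4 at both times.

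Single genes reversed as follows, and the cause was not tested. With the mean of a gene's probe sets, SQSTM1 at 24 h was -0.0071, ATF6 at 24 h 0.22, and at 72 h CDC25C 0.11, ZEB1 0.0026 and RWDD2B 0.053. With chip lot as a block, AGO4 at 72 h was 0.17 and PDK1 0.017. Without esiRNA, IRF9 at 24 h was 0.12, HUNK at 24 h -0.067 and BACH2 at 72 h -0.059. Without siRNA1, BACH2 at 24 h was 0.026, ISG15 at 24 h -0.017 and GDF15 at 72 h -0.16. Without siRNA2, SLBP was 0.092, MAP1LC3B 0.074, MSMO1 0.041, HSPA4L 0.56 and NDUFA8 0.25 at 24 h and ZEB1 0.0028 at 72 h. With siRNA2 alone, the difference between times was -0.1 for SLC13A4, 0.075 for SH2D3A and 0.081 for TMEM175. The background probe sets of BACH1 gave -0.031 and -0.019 at 24 h and 0.11 and 0.016 at 72 h.

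With each array left out in turn, BACH1 lay between -2.56 and -2.45 at 24 h and between -3.02 and -2.61 at 72 h. The shared calls ranged from 205 (without esiRNA 24 h replicate 3) to 432 at 24 h, from 253 to 382 at 72 h and from 11 to 21 at both times. The mean effect ranged from 2363 to 3289 and from 2842 to 3981, esiRNA from 2176 to 2914 and from 2996 to 3391, siRNA1 from 2458 to 3537 and from 3734 to 5056, and siRNA2 from 1478 (without siRNA2 24 h replicate 2) to 2400 and from 2900 to 3964. The F-test ranged from 4264 to 5114 and from 7018 to 7807, the difference between times from 2598 to 3703 and the mock times from 6814 to 7487. The number of lists stayed at 1 at 24 h and 3 at 72 h, though the unfolded protein response left the latter without mock 72 h replicate 3 (adjusted p = 0.873).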

Other observations

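The lists for the siRNA2 comparison between times, and the comparison of a type with itself across times, were chosen after the data were seen. The effects of siRNA2 at 24 h and at 72 h, which share no array, called 519 genes higher at both times against 221 expected (Fisher's exact one-sided p = 1.04e-99) and 531 lower against 128 expected (p = 4.52e-269), with 93 opposite against 393 and an r of 0.515 across genes. For siRNA1 these were 499 higher against 347 and 482 lower against 308, with an r of 0.171, and for esiRNA 314 against 241 and 367 against 212, with an r of 0.0703, both across sets of arrays summarized apart. Among genes called with siRNA2 and no other type at 24 h, TMEM255A, TMA16 and PAQR3 were lower with siRNA2 again at 72 h by -2.63, -1.54 and -1.06. Among list members, PSMB5, a catalytic subunit of the proteasome (-1.60 and -1.47), TXN, thioredoxin (-1.42 and -0.89), MAP1LC3B of autophagosomes (-1.08 and -1.29) and HSPA4L, a chaperone (-1.73 and -1.44), were lower with siRNA2 at both times. With siRNA1, STS (-2.44 and -2.23) and PPIF (-1.87 and -2.13) were lower at both times.

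Targets of p53, which large T antigen binds in these cells, were tested by reagent. With siRNA1 16 of 25 tested members were higher and 2 lower at 24 h (median 0.38, camera adjusted p = 0.00513, and adjusted p = 0.48 with an estimated correlation) and 16 and 2 at 72 h (0.31, adjusted p = 8.75e-06, and 0.26 with an estimated correlation). With siRNA2 at 72 h 1 was higher and 12 lower (-0.34, adjusted p = 0.0201, but 0.0511 without the members shared with other lists, and 0.59 with an estimated correlation). The hypoxia and glycolysis list had 11 of 32 members higher and 2 lower with siRNA1 at 72 h (0.12, adjusted p = 0.00122, and 0.95 with an estimated correlation) and 0 higher and 17 lower with siRNA2 (-0.33, adjusted p = 2.01e-05, and 0.59 with an estimated correlation). Further lists passed with siRNA1 at 72 h, namely cholesterol synthesis (0 and 13 of 19, -0.55, adjusted p = 0.000486, and 0.45 with an estimated correlation), the proteasome (0 and 13 of 27, -0.22) and the respiratory chain (1 and 22 of 47, -0.18), the last 2 at an adjusted p = 0.0419 (0.95 with an estimated correlation). The unfolded protein response passed with siRNA2 at 72 h (2 and 13 of 28, -0.53, adjusted p = 0.0042, and 0.72 with an estimated correlation). Whether the lists differed between reagents was not tested.

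Between 24 h and 72 h the siRNA2 effect alone moved down for hypoxia and glycolysis (0 up and 12 down, median -0.50, adjusted p = 2.07e-06), the unfolded protein response (0 and 6, -0.66, adjusted p = 0.00211) and p53 targets (0 and 9, -0.35, adjusted p = 0.0163). Relative to the other genes, camera's direction was up for the proteasome (0 of 27 members called, median 0.08, adjusted p = 0.00935) and cholesterol synthesis (2 and 0 of 19, median 0, adjusted p = 0.028), without a rise of their members as such. Each of these 5 lists had an adjusted p = 0.795 with an estimated correlation.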
